A study of Mus musculus with 2 samples.

How the data were processed

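RNA from mouse primary CD11b-positive cells (CD11b is integrin alpha M, a surface protein of myeloid cells) was compared between wild type (wt) and animals lacking interferon regulatory factor 8 (IRF8 KO). Per the labels, the cells were untreated, total RNA was extracted with Trizol, and each of 2 two-colour arrays carried wt RNA labelled with Cy5 and IRF8 KO RNA labelled with Cy3. No dye was exchanged between arrays, so that a dye effect of a probe and an effect of the genotype cannot be told apart by the design. The series describes the arrays as 2 biological replicates, and no label names the animals, the tissue or how CD11b-positive cells were selected.

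The deposited log2 values are normalized ratios of Cy5 over Cy3, made with the median (50th percentile) option of the mAdb array database, per the file headers. The deposited intensities are raw Cy5 and Cy3 signals, each the mean intensity of a spot minus its median background, per the file headers. Control features were excluded, a spot was kept on an array only where the signal was at least 100 and at least 1 times the background in both channels, and the strongest of several spots of the same well was kept, per the file headers. This filter can remove a transcript that 1 of the genotypes hardly expresses, which takes the strongest differences out of the comparison. Each deposited log2 ratio equalled the log2 ratio of the raw signals plus a constant, 0.026 for replicate 1 and 0.392 for replicate 2, so that the normalization did not remove a dependence on brightness. The median deposited ratio over listed probes was -0.0004 for replicate 1 and 0.3052 for replicate 2, so the second array was not centred on 0. A deposited value table held the same log2 ratios, but its columns for replicates 1 and 2 held the values that the array names in the larger table give to replicates 2 and 1. The array names were followed here. Both arrays have the same dyes and enter each mean alike, so the means, the tests and the counts do not depend on this choice, and only the statement of which array is replicate 1 does.

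The table listed 9143 probes, 6119 of them on replicate 1 and 8702 on replicate 2. The comparison used the 5678 probes (62.1%) listed on both arrays; 441 were listed on replicate 1 only and 3024 on replicate 2 only. Signals reached 65072, close to the top of the scanner's range, and 151 probes on both arrays had a channel at 60000 or more, where a ratio can be compressed. The number of arrays limits the precision of every value. Gene names came from the deposited annotation. Of 8459 probes with an Entrez gene ID, 8370 were found in a RefSeq gene table, used for names only, and 836 symbols were updated. Probes without a symbol (456) were kept under their probe ID, and 293 probes matched more than 1 gene ID. Positions are those of the probes on mouse build 37 as the deposited table gives them, with a median span of 71 bases. No genome or exon annotation of that build was used here. No probe carried the name Irf8, so the targeted gene was not analysed here, and Bcl2l1 and Fas, which were to be named beforehand, were not measured on both arrays.

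Ratios were turned to IRF8 KO over wt by the dyes in the labels, with no further centring, and probes of a gene were averaged, which gave 5192 genes, 433 of them with more than 1 probe. Each gene's 2 ratios were tested against 0 with limma 3.58.1 (R 4.3.3; lmFit with an intercept, eBayes), two-sided, with Benjamini-Hochberg adjustment over the 5192 genes and a threshold of 0.05. With 1 residual degree of freedom per gene, eBayes estimated an infinite prior degree of freedom and gave every gene the same SD of 0.56 and the same standard error of 0.40. The test therefore did not use a gene's own spread and amounted to a mean log2 ratio of at least 1.18 in size. With centred arrays the prior degrees of freedom were 7.4, so a gene's own spread counted there. Counts of genes at least 2-fold in the same direction on both arrays stand beside the test as a rule of size that needs no variance estimate. With 2 arrays, the smallest two-sided p of an exact sign-flip test is 0.5 for a single gene.

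The 26 gene lists were fixed before the data were examined, as were the main test, the rule for named genes and most alternatives. They cover neutrophil granules, mature neutrophils, monocytes and macrophages, dendritic cells, B cells, T cells, NK cells, erythroid cells, megakaryocytes and platelets, eosinophils with basophils and mast cells, stem and progenitor cells, MHC class II and class I presentation, the type I and gamma interferon responses, apoptosis regulators, ceramide and sphingolipid metabolism, lysosomal proteins, the cell cycle, inflammatory cytokines and chemokines, the immediate early and stress response, effectors of myeloid-derived suppressor cells, myeloid transcription factors, glycolysis, ribosomal proteins and a check of sex. The 19 lists with at least 5 genes on both arrays were tested with limma's camera (preset correlation 0.01), which compares a list with the other genes, with Benjamini-Hochberg adjustment over the lists. List values are medians of the genes' mean log2 ratios minus the median over all 5192 genes. Camera tests the mean of the members' statistics and not this median. A shift said below to be called, to pass or to miss is that of a list for which camera gave this result. The rule named the 12 highest and the 12 lowest genes by mean log2 ratio among those that passed limma and were at least 2-fold on both arrays, then up to 4 members of each list with the largest mean among those with the same sign on both arrays, then Irf8, Asah1, Bcl2l1, Bax and Fas. Predicted and unnamed entries were to be skipped, and 0 were met. Of the genes under this rule, 2 are not reported here. Any other gene named was chosen after its values were seen.

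Alternatives were arrays centred on their median, loess within each array (span 0.3), a filter at the 25th percentile of intensity, the other deposited table, the brightest probe per gene, arrays scaled to each other, probes tested singly, robust and intensity-trend eBayes, an adjusted p of 0.1, an ordinary t statistic, 1.5-fold and 3-fold limits, camera with an estimated correlation, fry, a background of named genes, and each array left out. Chosen after seeing the data were calls with the same direction on both arrays, calls also 2-fold on both, and runs without probes at 60000 or more or without probes matching several genes. KEGG pathways, as the deposited annotation assigns them, were also tested after the data had been seen. Permutation tests between lists drew 100000 permutations of genes. The pipeline was tested on simulated ratios of 5192 genes with 200 changed genes and an SD of 0.43. Over 20 runs, 30.2% of 2-fold, 98.6% of 4-fold and all 8-fold changes were called and 1.2% of calls were unchanged genes. In those runs camera called a list of genes shifted by 2-fold 20 times and an unchanged list 0 times. Estimated correlations within the real lists reached 1.00. With 2 arrays, such a value means only that all members differed between the arrays in the same direction. The simulated genes were independent and shared 1 SD, which real genes need not. The runs therefore do not show how correlation within a list or unequal spread affects the calls. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.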

Results

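Gene expression was measured in CD11b-positive mouse cells without IRF8, a transcription factor of the interferon regulatory factor family that directs myeloid cell development, against wt cells on 2 two-colour arrays. The question, per the title of the series, was which genes IRF8 regulates in these cells. Median raw signals on replicate 1 were 1652 for wt (Cy5) and 1755 for IRF8 KO (Cy3), and on replicate 2 they were 2448 and 2584. Irf8 itself was not analysed here, since 0 probes carried its name, so that the genotype labels have no check from the targeted gene and each direction rests on the dyes in the labels. All values below are log2 ratios of IRF8 KO over wt, with n = 2 arrays.

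Gene lists of neutrophil granules and the cell cycle lay higher in IRF8 KO cells, and those of macrophages, dendritic cells and MHC class II presentation lower, by camera with a preset correlation. None of these 5 calls held with an estimated correlation (adjusted p = 0.47 for each). That setting of camera rests on 1 residual degree of freedom, and its lowest unadjusted p over the 19 lists was 0.12. Its failures, here and below, were therefore close to fixed by the 2 arrays. They do not speak against a single list, and they leave the calls with the preset correlation unchecked. Of 6 dendritic cell genes 0 passed after centring and 5 with loess. Camp, an antimicrobial peptide of neutrophil granules, was 11.7-fold higher in KO (log2 3.55 ± 1.58, SD), and Csf1r, the receptor for macrophage colony-stimulating factor, was 6.35-fold higher in wt (log2 -2.67 ± 0.53). Both had a channel at 60000 or more, where a ratio can be compressed, so these folds are approximate. Of 5192 genes measured on both arrays, 323 passed limma, 146 higher and 177 lower in KO. The median over all genes was 0.03 on replicate 1 and -0.42 on replicate 2, and -0.21 for the mean of the arrays. With each array centred on its median, 160 genes were higher and 79 lower, with 66.9% of the calls higher against 45.2%. The centred run also had 7.4 prior degrees of freedom in place of an infinite number, so a gene's own spread entered the test. For calls lost there, here and below, offset and spread were not separated for each gene. Flt3 moved only from -1.51 to -1.36, still past the 1.18 in size that the main test asked for. Loess, which also removes an array offset, kept all 177 lower calls, although it changes a dependence on brightness too. This argues against the offset alone as what ended the lower calls. Centring raised the mean ratios, so the offset cannot have ended calls of genes higher in KO, such as Chil3 and Pglyrp1 below. Loess within arrays gave 384 higher and 278 lower (58.0%). An ordinary t statistic called 0 genes. It gave 302 of the 5192 genes an unadjusted p under 0.05, close to the share of 0.05 that no difference at all would give. Limma gave 839 such genes, and its calls rest on a spread shared by all genes.

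A larger set of genes moved alike on the arrays than independent arrays would give. At least 2-fold on both arrays were 112 genes higher in KO, against 10.3 for independent arrays, and 143 genes lower, against 34.8, while 20 genes were 2-fold in opposite directions. Single arrays gave 396 and 135 genes 2-fold higher and 281 and 643 genes 2-fold lower on replicates 1 and 2. The ratios of the arrays correlated across genes with Pearson's r = 0.54 and Spearman's rho = 0.42; genes are not independent replicates. Of the 323 calls, 233 were also 2-fold on both arrays and 3 had opposite signs on the arrays, namely Chil3 (3.26 and -0.21 on replicates 1 and 2), Marco (-2.76 and 0.03) and Igh-VJ558 (0.47 and -3.73), the first and last with a channel near the ceiling, named after their values were seen.

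**Figure D1:**
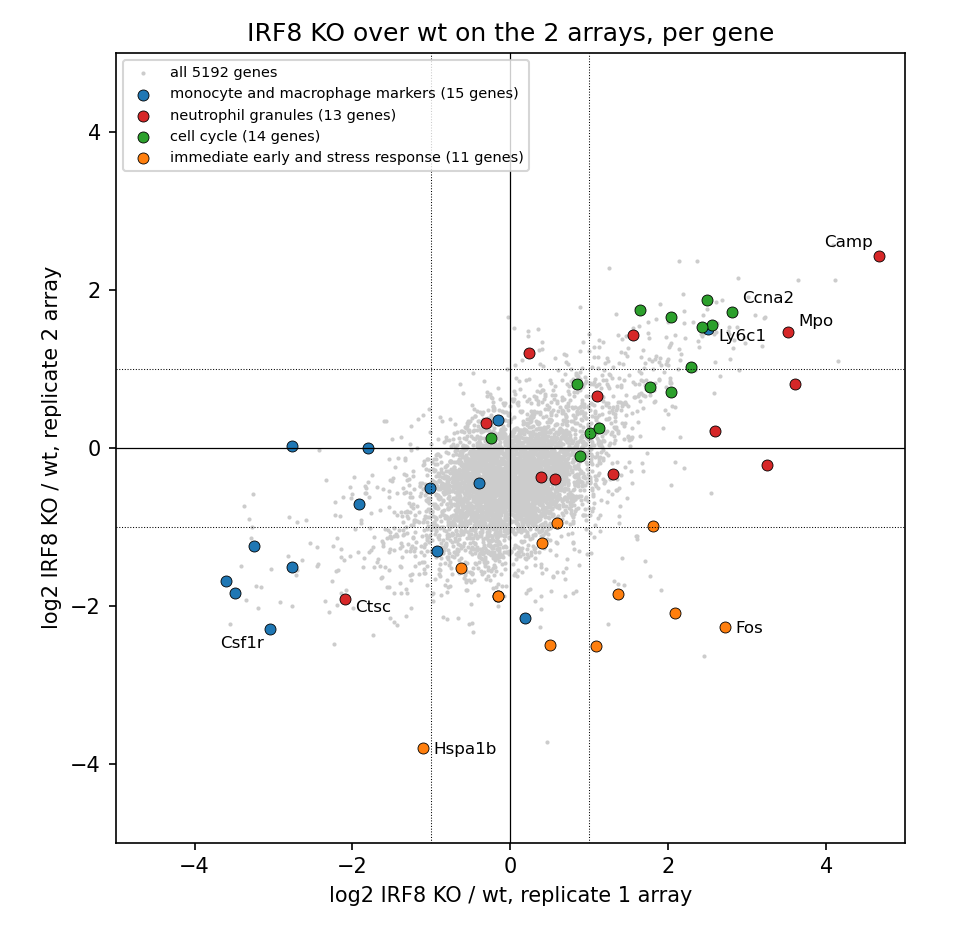
Log2 ratio of IRF8 KO over wt on replicate 1 (x axis) and replicate 2 (y axis) for 5192 genes (grey points), with 4 gene lists in colour and dotted lines at 2-fold. Camp lies at 4.66 and 2.43 and Csf1r at -3.04 and -2.30, while Fos lies at 2.71 and -2.27, on opposite sides of 0.

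The 12 highest genes rose 5.16-fold to 11.7-fold in KO. Camp (chromosome 9, 109750020 to 109750090) gave 4.66 and 2.43 on replicates 1 and 2 (adjusted p = 3.89e-15), with a channel near the top of the scanner's range. Next were Abca13, a lipid transporter of the ABC family (3.32 ± 1.07, SD; chromosome 11, 9583462 to 9583532; adjusted p = 2.56e-13), Ceacam10, a member of the carcinoembryonic antigen family (3.12 ± 1.40), and Anxa1, a calcium-dependent phospholipid-binding protein (2.88 ± 1.07). Mpo, the peroxidase of primary granules, stood at 2.49 ± 1.45, and the chitinase-like Chil4 at 2.62 ± 2.16, each with a channel near the ceiling. Dstn, an actin-depolymerising factor, rose by 2.52 ± 0.52, Ero1a, an oxidase of the endoplasmic reticulum, by 2.44 ± 1.10, and Megf9 by 2.43 ± 1.11. The mitotic spindle gene Spag5 rose by 2.39 ± 1.01. The histone genes H2ac24 (2.46 ± 0.78) and H4c4 (2.37) completed the set, and the H2ac24 probe matched several genes.

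The 12 lowest genes fell to between 5.24-fold and 7.43-fold below wt. Ms4a6c, a membrane protein of the MS4A family, was lowest at -2.89 ± 0.93 (chromosome 19, 11545604 to 11545674; adjusted p = 5.76e-10). Csf1r (chromosome 18, 61290398 to 61290468; adjusted p = 1.95e-08) had a channel near the ceiling. Hmox1, which degrades heme, stood at -2.66 ± 1.16 and Lrp1, an endocytic receptor, at -2.64 ± 1.01. Phf11a (-2.61 ± 0.82), the adhesion receptor Adgre4 (-2.49 ± 1.04), the Fc receptor Fcgrt (-2.46 ± 0.99) and Tmem176b (-2.46 ± 1.36) followed. Ctss, the protease that trims the class II invariant chain, fell by 2.43 ± 0.69 and Tbc1d9 by 2.39 ± 0.54. The heat shock gene Hspa1b reached -2.45 ± 1.91 from -1.10 and -3.81, so that replicate 2 set most of its mean, and it too had a channel near the ceiling.

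**Figure D2:**
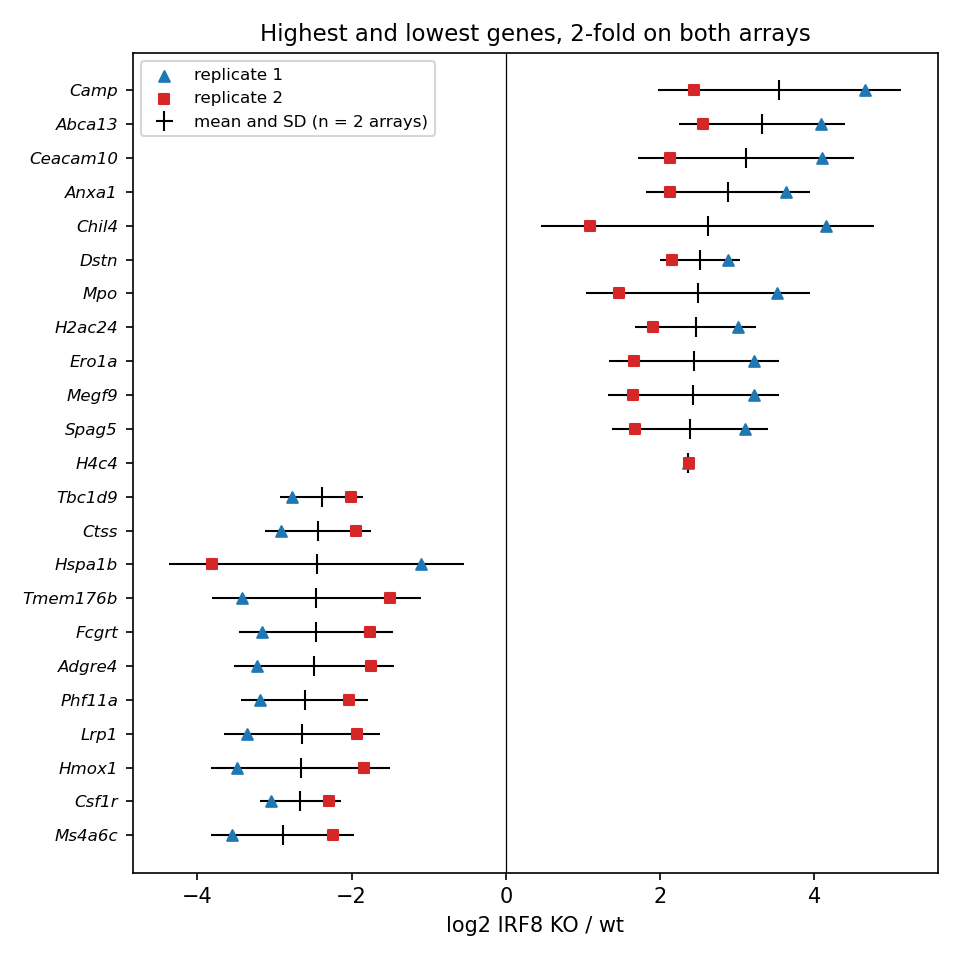
Log2 ratio of IRF8 KO over wt (x axis) of the genes named as highest and lowest, with each array's value (triangles, replicate 1; squares, replicate 2), the mean (tick) and the SD of n = 2 arrays (line). Each gene lies on 1 side of 0 on both arrays, from Camp at 3.55 to Ms4a6c at -2.89.

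Among neutrophil granule genes, 6 of 13 rose and 1 fell. Camp, Mpo and Ngp (2.21, from 3.60 and 0.81) rose, and Cybb, the NADPH oxidase subunit, rose by 1.49 ± 0.09. The genes Chil3 and Pglyrp1 (2.59 and 0.21) were called on the strength of replicate 1, both with a channel near the ceiling, and neither passed after centring (adjusted p = 0.19 and 0.10). Ctsc, the protease that activates granule serine proteases, fell by 2.01 ± 0.13. Adjusted over the list alone, 7 rose and 1 fell. The list's median lay 1.09 above that of all genes (1.28 and 0.74 on replicates 1 and 2; camera adjusted p = 2.2e-10; adjusted p = 0.47 with an estimated correlation).

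Of 9 mature neutrophil markers, the formyl peptide receptor Fpr1 rose (1.30 ± 0.50) and the cytokine Il1b fell (-1.38 ± 1.21), a call that ended with centring (adjusted p = 0.11). Gfi1, a transcription factor of granulocytes, stood at 1.11 ± 0.65 (adjusted p = 0.0773) and Mmp25 at 0.42 ± 0.59 (adjusted p = 0.709). Adjusted over the list alone, 3 rose and 1 fell. The list lay 0.42 above all genes (camera adjusted p = 0.033; adjusted p = 0.72 with an estimated correlation), from 0.84 on replicate 1 and -0.01 on replicate 2, so its direction rested on replicate 1. The call also ended without probes near the scanner's ceiling (adjusted p = 0.082).

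Monocyte and macrophage markers fell in 7 of 15 cases and rose in 1. Csf1r, Hmox1 and Spic, a transcription factor of red pulp macrophages (-2.25 ± 1.42), fell, as did the adhesion molecule Vcam1 (-2.14 ± 0.89). Mpeg1 (-1.31 ± 0.85) and Marco fell without centring and did not pass with it (adjusted p = 0.14 and 0.34). Ly6c1 rose by 2.00 ± 0.70, with a probe that matched several genes. Adjusted over the list alone, 11 fell and 1 rose. The list's median lay 0.91 below all genes (a shift of -0.91; -1.83 and -0.83 on replicates 1 and 2; camera adjusted p = 1.5e-09; adjusted p = 0.47 with an estimated correlation).

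Dendritic cell markers fell in 5 of 6 cases, both over all genes and adjusted over the list alone. Flt3, a growth factor receptor of progenitors and dendritic cells, stood at -1.51 ± 0.92, Bst2 at -1.50 ± 0.67, Ly6d at -1.48 ± 0.96 and Cd83 at -1.30 ± 0.21. None of the 5 passed after centring (0 calls), where these 4 stood at -1.36, -1.34, -1.33 and -1.15 with adjusted p from 0.054 to 0.097, and all 5 passed with loess. The list's shift was -1.19 (-1.43 and -0.52 on replicates 1 and 2; camera adjusted p = 0.00014; adjusted p = 0.47 with an estimated correlation), and the call held after centring (adjusted p = 0.00071) and with loess (adjusted p = 0.00019).

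MHC class II presentation fell in 4 of 10 genes over all genes and in 7 adjusted over the list alone, and all 10 were lower on both arrays. H2-Ab1, a chain of the class II molecule, fell by 1.66 ± 0.26 with a channel near the ceiling, Cd74, the invariant chain, by 1.37 ± 0.70, and Ifi30, a lysosomal thiol reductase, by 1.30 ± 0.09, beside Ctss. After centring 2 of the 4 passed, and Cd74 and Ifi30 did not (adjusted p = 0.060 and 0.062). The list's shift was -0.76 (-0.83 and -0.74 on replicates 1 and 2; camera adjusted p = 6e-06; adjusted p = 0.47 with an estimated correlation). Macrophage, dendritic and B cell markers lay below all genes as well, the last by a shift of -0.50.

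B cell markers had 0 of 10 genes called, and 2 fell adjusted over the list alone. Vpreb3 stood at -1.09 ± 0.61 (adjusted p = 0.0821), Fcer2a at -1.05 ± 1.24, Cd79b, a chain of the B cell receptor, at -0.90 ± 0.92, and Blnk at -0.86 ± 1.04. The shift was -0.17 on replicate 1 and -1.02 on replicate 2 (camera adjusted p = 0.011; adjusted p = 0.72 with an estimated correlation), and the call ended with an intensity trend in eBayes (adjusted p = 0.052). MHC class I presentation had 0 of 12 genes called, also adjusted over the list alone, and a shift of -0.16 (-0.14 and -0.27 on replicates 1 and 2; camera adjusted p = 0.24). Its members with the largest ratios were Psme1 (-0.75 ± 0.27), H2-Q7 (-0.65 ± 0.69; its probe matched several genes), Psmb8 (-0.64 ± 0.50) and H2-D1 (-0.54 ± 0.73).

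Of 14 type I interferon response genes, 4 fell, and 5 adjusted over the list alone: Ifi204 (-2.28 ± 1.06), Ifi205 (-2.15 ± 0.29; its probes matched several genes), Bst2 and Irf7 (-1.23 ± 0.17), the last 2 not after centring (adjusted p = 0.073 and 0.080). The list was called lower by camera (adjusted p = 0.0071, and 0.47 with an estimated correlation), which tests the mean of the members. Their mean log2 ratio was -0.66, whereas the median member barely moved, with a shift of -0.18 (-0.17 and -0.07 on replicates 1 and 2). Macrophage and dendritic cell markers lay lower as well, by shifts of -0.91 and -1.19, and Bst2 is also a member of the dendritic cell list. Of 13 interferon gamma response genes, the GTPases Ifi47 (-1.76 ± 0.49) and Gbp5 (-1.34 ± 0.35) fell and Cybb rose, while Cd274 stood at -1.12 ± 0.75 (adjusted p = 0.0729). Gbp5 did not pass after centring (adjusted p = 0.05), and adjusted over the list alone 6 fell and 1 rose. The interferon gamma list had a shift of -0.60 and a mean log2 ratio of -0.52. It missed the threshold (camera adjusted p = 0.057, and 0.72 with an estimated correlation). It passed with centred arrays (camera adjusted p = 0.046), loess (0.047) and without probes matching several genes (0.049).

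Cell cycle genes rose in 9 of 14 cases, also adjusted over the list alone, and the same count passed after centring. Neutrophil granule genes lay higher and macrophage markers lower on the same arrays, by shifts of 1.09 and -0.91. Ccna2, the S and G2 phase cyclin, rose by 2.27 ± 0.77, Birc5, a protein of the mitotic passenger complex, by 2.18 ± 0.44, the mitotic transcription factor Foxm1 by 2.05 ± 0.71 and Stmn1, which destabilises microtubules, by 1.98 ± 0.63. The proliferation marker Mki67 rose by 1.37 ± 0.93. Pcna (0.39) and Rrm1 (-0.06) were not called. The list's shift of 1.72 was the highest of the 19 (1.87 and 1.34 on replicates 1 and 2, camera adjusted p = 3.4e-18, adjusted p = 0.47 with an estimated correlation). The larger KEGG cell cycle pathway of 50 genes, tested after the data had been seen, had a shift of only 0.24 (0.26 and 0.22 on replicates 1 and 2). In it 6 genes were called higher and 1 lower (camera adjusted p = 0.034, adjusted p = 0.99 with an estimated correlation).

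**Figure D3:**
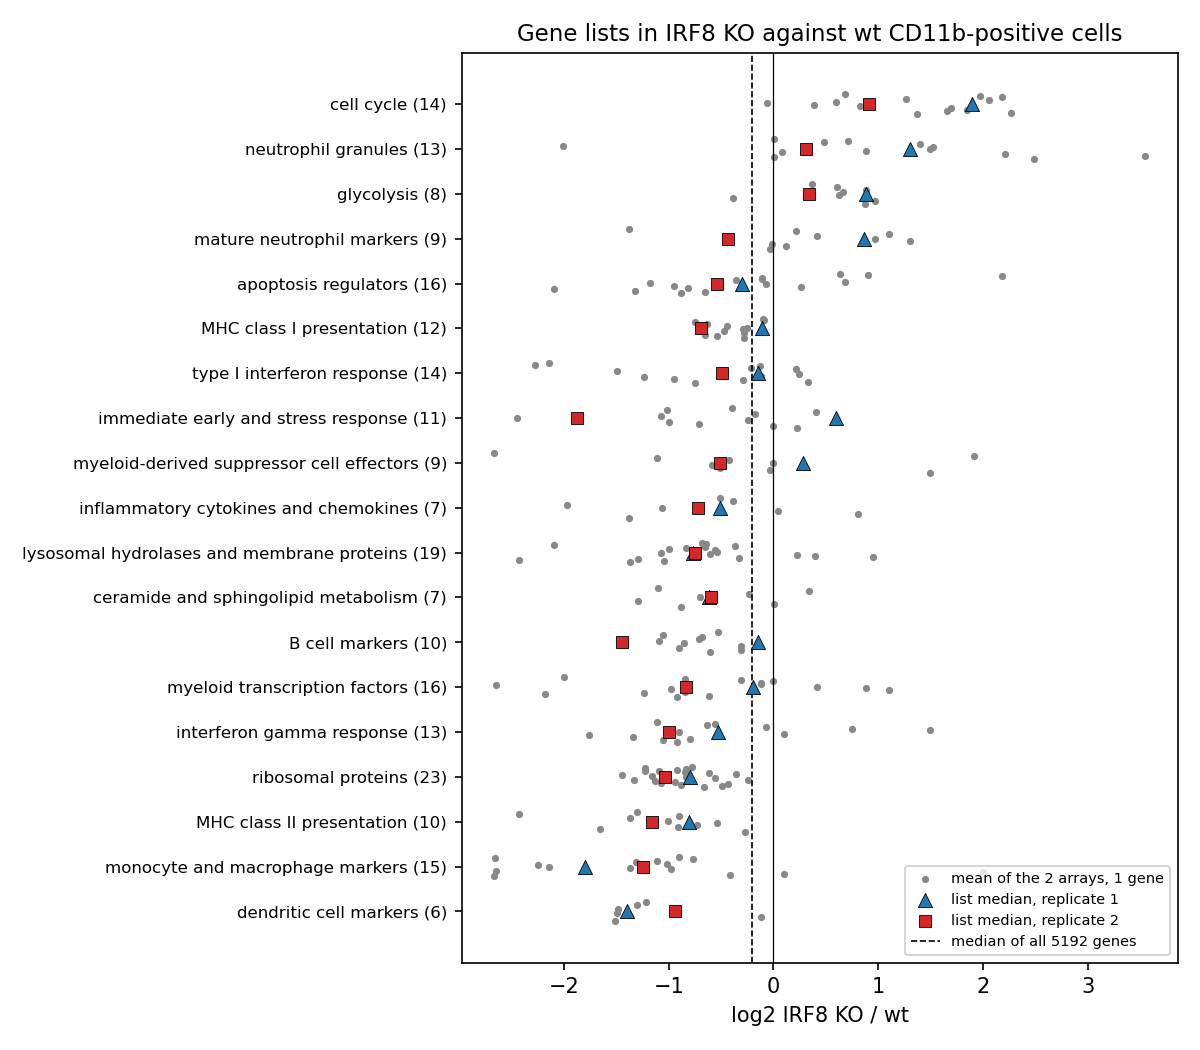
Log2 ratio of IRF8 KO over wt (x axis) for 19 gene lists (number of genes in brackets), with each gene's mean of the 2 arrays (grey points), list medians on replicate 1 (triangles) and replicate 2 (squares) and the median of all 5192 genes at -0.21 (dashed line). Cell cycle medians lie at 1.90 and 0.92, and monocyte and macrophage medians at -1.80 and -1.25.

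Apoptosis regulators changed in both directions, with 1 of 16 higher and 3 lower, the same numbers adjusted over the list alone. Birc5 rose, and Bcl2a1d (-2.10 ± 1.02) and Bcl2a1b (-1.32 ± 0.97), prosurvival genes whose probes matched several genes, fell with Casp1, the inflammatory caspase (-1.18 ± 0.07). Bcl2a1b and Casp1 did not pass after centring (adjusted p = 0.16 and 0.084). Bax, a proapoptotic gene, stood at -0.81 ± 0.41 (adjusted p = 0.28). The list's shift was -0.03, against -0.33 and -0.12 on replicates 1 and 2 alone (camera adjusted p = 0.71). Of 7 ceramide and sphingolipid genes, the ceramide synthase Cers5 fell (-1.30 ± 0.32; adjusted p = 0.079 after centring), and 2 fell adjusted over the list alone. Psap stood at -1.11 ± 0.18 (adjusted p = 0.0771), Asah1, the acid ceramidase, at -0.88 ± 0.58 (adjusted p = 0.221) and Sgms1 at -0.70 ± 0.12. That list's shift was -0.49, from -0.64 on replicate 1 and -0.17 on replicate 2 (camera adjusted p = 0.12).

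Lysosomal genes fell in 4 of 19 cases, and adjusted over the list alone 7 fell and 1 rose. Beside Ctss, the proteases Lgmn (-2.10 ± 0.14), Ctsb (-1.37 ± 1.36) and Ctsz (-1.29 ± 0.03) fell, of which Ctsb and Ctsz did not pass after centring (adjusted p = 0.22 and 0.060). The shift was -0.45 (-0.79 and -0.32 on replicates 1 and 2, camera adjusted p = 0.0004, adjusted p = 0.47 with an estimated correlation). The larger KEGG lysosome pathway of 64 genes, tested after the data had been seen, was not called (camera adjusted p = 0.086). Its shift was -0.24 (-0.42 and -0.08 on replicates 1 and 2), with 2 genes higher and 6 lower. Monocyte and macrophage markers lay lower on the same arrays, by shifts of -1.83 and -0.83. Myeloid transcription factors fell in 4 of 16 cases (6 fell and 1 rose adjusted over the list alone), among them Irf5 (-2.18 ± 0.15), Zeb2 (-2.15 and -1.85 on replicates 1 and 2) and Irf7. Their shift was -0.52, against -0.22 and -0.41 on replicates 1 and 2 alone (camera adjusted p = 0.0059; adjusted p = 0.47 with an estimated correlation).

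Cytokines and chemokines had 2 of 7 genes lower, Ccl9 (-1.97 ± 0.67) and Il1b, and 3 adjusted over the list alone, with Ccl6 at -1.07 ± 0.03 (adjusted p = 0.0927) and Tnf at 0.81 ± 0.06 (adjusted p = 0.281). The shift was -0.31 (-0.54 and -0.30 on replicates 1 and 2; camera adjusted p = 0.057; adjusted p = 0.59 with an estimated correlation). It was -0.58 and passed with the filter on dim spots (adjusted p = 0.014), and passed without probes matching several genes (adjusted p = 0.049). Of 9 effectors of myeloid-derived suppressor cells, the vascular growth factor Vegfa (1.92 ± 0.71) and Cybb rose and Csf1r fell, and adjusted over the list alone 2 rose and 2 fell. That list's shift was -0.21, from 0.25 on replicate 1 and -0.08 on replicate 2 (camera adjusted p = 0.85).

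Of 11 immediate early and stress genes, 8 were higher in KO on replicate 1 and lower on replicate 2, and 3 (Hspa1b, Hspa8 and Nr4a1) were lower on both. The median member lay 0.57 above all genes on replicate 1, and the shift was -1.45 on replicate 2. Fos, a subunit of the AP-1 transcription factor, gave 2.71 and -2.27, Jun gave 2.08 and -2.10, and Junb gave 1.08 and -2.50. Only Hspa1b was called, and 4 fell adjusted over the list alone; Hspa8 stood at -1.07 ± 0.63 and Nr4a1 at -1.01 ± 1.22. The list's shift of -0.19 for the mean of the arrays (camera adjusted p = 0.042; adjusted p = 0.73 with an estimated correlation) did not pass after centring (adjusted p = 0.13), loess (0.081), the filter on dim spots (0.054), an intensity trend (0.11) or without probes near the ceiling (0.26).

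Glycolysis genes had 0 of 8 called, also adjusted over the list alone, and 7 of 8 were higher on both arrays. Gpi1 (0.97 ± 0.92; its probe matched several genes), Pgk1 (0.88 ± 0.29), Hk2 (0.88) and Tpi1 (0.67 ± 0.21) had the largest ratios. The shift was 0.85 (0.86 and 0.77 on replicates 1 and 2; camera adjusted p = 0.0013; adjusted p = 0.67 with an estimated correlation), and loess within arrays called 6 of the 8. Ribosomal protein genes fell in 4 of 23 cases and in 11 adjusted over the list alone, with 22 of 23 lower on both arrays. Rplp1 (-1.45 ± 0.07), Rpl13 (-1.33 ± 0.36) and Rps6 (-1.23 ± 0.13) were among those called, each with a probe that matched several genes and Rpl13 with a channel near the ceiling, and only Rplp1 passed after centring (adjusted p = 0.037). The shift was -0.67 (-0.83 and -0.61 on replicates 1 and 2; camera adjusted p = 1.4e-06; adjusted p = 0.52 with an estimated correlation).

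Other cell types had too few genes on both arrays for a list test. Of 2 T cell markers, Cd2 fell (-1.23 ± 1.04; adjusted p = 0.13 after centring) and Thy1 stood at -0.31 ± 0.42. NK cell markers Klrk1 (-0.76 ± 0.39) and Klrg1 (-0.14 ± 0.18) did not pass, nor did the erythroid genes Hbb-b1 (-1.10 ± 0.33; its probe matched several genes) and Epor (-0.85 ± 0.01). Ear1, of eosinophils, stood at 0.72 ± 0.49, with a probe that matched several genes. Among 4 stem and progenitor genes Flt3 fell, and Spi1 stood at -0.85 ± 0.34 (adjusted p = 0.253). Megakaryocyte markers and the check of sex had 0 genes on both arrays.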

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

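The tests of explanations here, on further probes of a gene, on loess medians of selected genes and on the difference between lists, were chosen only after the results had been seen.

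Genes listed on a single array took no part in the comparison and have no replicate, yet many differed by 2-fold or more. Of 382 genes listed on replicate 1 only, 5 were at least 2-fold higher and 58 at least 2-fold lower in KO. Of 2386 genes listed on replicate 2 only, 154 were at least 2-fold higher and 104 at least 2-fold lower. All 6 monocyte and macrophage markers of this kind were on replicate 1 and 2-fold lower there, with C1qc, a complement component, at -3.98, Timd4 at -2.89, Adgre1 at -2.84, Mertk at -2.38 and Cd5l at -1.04, and Cd68 8-fold lower. All 5 neutrophil granule genes were on replicate 2 and 2-fold higher there, with the protease Ctsg at 2.38, Mmp8 at 2.13, Padi4 at 1.97, Orm1 at 1.84 and Mmp9 at 1.37. Of 5 mature neutrophil markers on replicate 2, 4 were 2-fold higher, namely Itgb2l (2.54), Fpr2 (2.44), S100a9 (2.16) and Mrgpra2a (1.85), and of 9 cell cycle genes on replicate 2, 4 were, among them Ccnb1 and Ccnb2 at 1.82. The 4 dendritic cell markers on a single array did not lie with the lower list on both arrays: 1 was 2-fold higher (Cd209a, 1.21, on replicate 2) and 0 were 2-fold lower, with values of 0.66 for the gene on replicate 1 and a median of -0.30 for the 3 on replicate 2. These genes were named after their values were seen.

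The 112 higher and 143 lower genes that were 2-fold on both arrays might be dye effects, since wt RNA was in Cy5 on both arrays. Genes whose first probe was 2-fold higher on both arrays had other probes in the same direction in 10 of 10 cases (100%, exact 95% interval 69.2 to 100, against 41.3% of all genes with further probes). This argues against probe-specific dye bias as the whole cause for those 10 genes. For the lower genes 4 of 5 did (80.0%, interval 28.4 to 99.5, against 58.7%), too few to exclude it. A dye effect shared by all probes of a gene would pass this check. Dye bias and genotype therefore cannot be told apart for the higher or the lower genes. Loess within arrays moved the median of the higher genes from 1.72 to 1.94 (quartiles 1.68 and 2.28). It moved that of the lower genes from -1.45 to -1.24 (quartiles -1.64 and -1.07), with 0 changes of sign in either set. Only 55 of the 143 lower genes were still 2-fold on both arrays. Median ratios of probes grouped by brightness ran only from -0.14 to 0.11 on replicate 1 and from -0.51 to 0.00 on replicate 2. Genes chosen at 2-fold on both arrays could therefore hardly change sign with loess. The check thus cannot decide on a dependence on brightness or an array offset as a cause. A lower share of macrophages alone would raise all other cell types alike. Neutrophil granule genes lay 1.69 above B cell markers in mean log2 ratio (permutation p = 0.00092 over genes, 1.45 and 1.76 by medians on replicates 1 and 2). The granule shifts were 1.28 and 0.74 and the B cell shifts -0.17 and -1.02, so on replicate 2 much of the gap was the low B cell list. A larger share of granule-producing cells in KO, fewer B cells in KO beside fewer macrophages, or a change within cells stays open and was not tested. The permutation p treats genes as independent and does not measure the spread between arrays. Members of a list can move together, which 2 arrays cannot measure. The estimated correlation of 1.00 within the B cell list means only that every member had its higher ratio on replicate 1. The median over all genes was higher there as well (0.03 against -0.42).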

How the results depend on the processing

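Chosen after the data had been seen were the runs without probes near the ceiling, without probes matching several genes, and on calls alike or 2-fold on both arrays; they gave 233 to 320 calls against 323. No paired analysis was possible because each ratio already sets KO against wt on the same array and there is a single group of arrays. Not run were normexp, for which background and foreground would be needed separately, a slide block, all settings for Irf8, and limma with an array left out, which leaves no residual degree of freedom. Centring used the median of all probes listed on an array, and moved the all-gene median of the arrays, -0.21, towards 0 without reaching it. It lowered the prior degrees of freedom from infinite to 7.4 and called 79 genes lower, all among the 177. After centring 83 genes were 2-fold lower on both arrays. Loess called 662 genes (384 higher, 278 lower), including all 323, and left 195 genes 2-fold higher and 58 lower on both arrays. The ordinary t statistic called 0 genes (0 higher, 0 lower; smallest adjusted p = 0.32), with no spread shared between genes. By construction, the 1.5-fold limit gave 687 genes (231 higher, 456 lower) and the 3-fold limit 52 (29 and 23). With an array left out, 677 to 778 genes were 2-fold on the array that remained, 135 to 396 higher and 281 to 643 lower, since agreement was no longer asked for. The correlation of the arrays rose with loess (r = 0.586, rho = 0.481) and without the dimmest spots (r = 0.595, rho = 0.489); the cause was not tested. Camera called 4 lists higher and 9 lower, but 0 and 0 with an estimated correlation (lowest adjusted p = 0.47) and 0 and 0 with fry (lowest adjusted p = 0.098), which both rest on 1 residual degree of freedom. With an array left out, the mature neutrophil shift ran from -0.014 to 0.836 and that of immediate early genes from -1.448 to 0.569, the first turning without replicate 1 and the second without replicate 2, for which no cause was tested. Of 266 other values of list shifts, 211 kept their call or, where untested, moved by less than 1 SD; 33 lost the call, 5 gained it, 15 moved further and 2 called ones reversed. Of the uncalled shifts, that of suppressor cell effectors turned from -0.21 to 0.25 without replicate 2, and that of apoptosis regulators from -0.03 to 0.09 without probes matching several genes. Of 901 values of 92 named genes, 863 stayed so, 25 lost the call and 13 gained it. Part of the 863, and part of the 211 list values, stayed by construction. With an array left out, a single gene's value always lies within 1 SD of the mean of 2 arrays. The other deposited table held the same ratios, so genes and lists could not change with it. Centring cannot move a list's shift relative to all genes, though it can change the call. Genes or lists called in neither setting also counted as kept. Centring ended 18 of the named genes' calls, all lower in KO, and loess gave the 13 gained. Signals over background could not be compared, as the background was not used here; spots at or above 60000 limit the ratios of the brightest genes.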

Other observations

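The tests here, of KEGG pathways, of an exchange of RNA and of B cells as a source, were chosen only after the results had been seen, and genes were named after their values were seen.

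Of 26 histone genes on both arrays, 9 rose and 0 fell, and 19 were higher on both arrays; centring also left 9 called and loess 16. H4c14 stood at 2.18 ± 1.10 (SD, n = 2; a channel near the ceiling), H2ac15 at 1.95 ± 0.69 and H4c9 at 1.87 ± 0.26, although probes of such near-identical genes can bind each other's transcripts. They were the 9 called genes higher among the 41 of the KEGG lupus pathway, which lay 0.64 above all genes (camera adjusted p = 7e-07; adjusted p = 0.99 with an estimated correlation). The KEGG ribosome pathway of 66 genes had a shift of -0.68 and 12 genes lower (camera adjusted p = 1.7e-11; adjusted p = 0.99 with an estimated correlation). Of 166 pathways tested, 9 were called higher and 6 lower, and 0 with an estimated correlation.

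Of 13 genes of the KEGG pentose phosphate pathway 2 rose, and of 13 of the starch and sucrose pathway 3 rose. G6pdx, the entry enzyme of the pentose phosphate pathway, rose by 1.52 ± 0.67 (limma adjusted p = 0.0044) and Pgd, its next dehydrogenase, by 1.45 ± 0.49. That pathway of 13 genes lay 0.53 above all genes (0.31 and 0.67 on replicates 1 and 2; camera adjusted p = 0.02; adjusted p = 0.99 with an estimated correlation), with the remaining 11 genes not called, among them Pfkl at -0.38 and Prps1l3 at -0.70. Pygl, the glycogen phosphorylase of liver and leukocytes, rose by 2.15 ± 0.88, the glycogen synthase Gys1 by 1.45 ± 0.70 and Ugdh by 1.44 ± 0.04, in the starch and sucrose pathway, which lay 0.25 above all genes and held Pygb at -0.79 (0.22 and 0.64 for the pathway on replicates 1 and 2; camera adjusted p = 0.016; adjusted p = 0.99 with an estimated correlation).

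Of 11 immediate early and stress genes, 8 were higher in KO on replicate 1 and lower on replicate 2, against 36.1% of all genes, with medians of 0.60 and -1.87; the difference between the arrays was not tested. An exchange of RNA or dyes on 1 array could turn these genes over, but would turn all genes over, and the arrays correlated at r = 0.54 over 5192 genes, which argues against it. Different handling of the cells of 1 sample before lysis, to which Fos, Jun and heat shock genes are known to respond, may be the cause, but 8 of 11 genes cannot decide it and no label gives the handling.

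MHC class II genes were lower in KO on both arrays, which could come from more B cells in the wt samples. On replicate 1 their mean ratio differed from that of the B cell markers by -0.82 (permutation p = 0.0069 over genes, medians -0.81 and -0.15). This argues against B cells as the whole cause on that array for the list as a set. Without genes near the scanner's ceiling the difference was -1.13 (permutation p = 0.0061). That check left out H2-Aa, H2-Ab1 and H2-Eb1 and leaned on Ctss (-2.92) and Ifi30 (-1.37), with H2-Ob at -0.13. It therefore says little about the class II chains. Both p-values treat the genes of a list as independent and do not measure a spread between samples. On replicate 2 the difference was 0.00 (permutation p = 0.99; medians -1.16 and -1.45; -0.13, p = 0.5, without genes near the ceiling), so there B cells and other causes cannot be told apart, as the B cell markers lay as low as the class II genes. Fewer macrophages or dendritic cells in KO and lower transcription in each cell were not tested and stay open on both arrays.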
